A study of Danio rerio with 4 samples.

How the data were processed

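RNA was extracted from whole zebrafish embryos at 24 h post fertilisation, and libraries were made with an Illumina TruSeq RNA kit after oligo(dT) enrichment, per the labels' protocols. For RIP-seq, the labels' protocols describe injection of Flag-tagged ddx39a mRNA into mutant embryos and recovery on anti-Flag beads, for the libraries of both genotype labels. Groups were taken from the assay and the genotype label of each of the 4 libraries, 1 library per group.

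The deposited values were raw counts per Ensembl gene, 1 file per library. Per the submitters' processing notes, the tools were bcl2fastq, FastQC 0.11.5, TopHat2 2.2.1, Bowtie2 2.2.3 and HTSeq 0.6.1p1, with the genome build GRCz10. The strand setting of the counting and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart. Each file had 31953 gene rows and 5 HTSeq summary rows. The summary rows were kept out of library sizes and ratios. Alignments to more than 1 place made up 11.2% and 8.42% of the records in wild-type and mutant RNA-seq. In RIP-seq they made up 91.8% with the wild-type label and 89.5% with the mutant label. These are shares of records and not of reads. Of uniquely aligned records, 53.8%, 54.0%, 82.1% and 79.2% fell in no gene. The counts of the authors therefore leave out most RIP-seq alignments, and ratios of multi-copy genes rest on their unique parts.

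Gene symbols came from a table that matched 26121 of the 31953 gene IDs. It often uses human-style symbols, and 1706 symbols are carried by more than 1 gene ID, so IDs are given where copies are told apart. A RefSeq gene table of another assembly was not used. Transcript lengths were not analysed here.

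For each pair of libraries, counts were scaled by TMM factors (edgeR 4.0.16, R 4.3.3) computed over that pair and given as CPM. Genes with a CPM of at least 1 in at least 1 of the 2 libraries were compared. The result per gene is the ratio of scaled counts with its 95% exact conditional binomial (Clopper-Pearson) interval. A gene was called higher or lower when the ratio was at least 2-fold and the interval excluded equality. Numbers of genes or list members given as at least 2-fold apart or as passing the size rule are numbers of called genes. No p-values across genes were computed, because there was 1 library per group. Where a library had 0 counts, the fold is a lower bound computed against a floor of 3 counts per library, equal to a CPM of 0.302 and 0.315 of the total in RNA-seq and of 1.53 and 1.34 in RIP-seq (wild-type and mutant label). Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

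There were 28 gene lists, fixed before the data were examined: fast skeletal muscle sarcomere, slow skeletal muscle, heart, myogenic regulators, lens, neural crest and cartilage, neural progenitors, neurons, erythroid, blood stem cell and leukocyte, endothelium, epidermis, hatching gland, notochord and floor plate, presomitic mesoderm and segmentation clock, pigment cells, yolk syncytial layer and liver, photoreceptor and retina, p53 targets, cell stress and unfolded protein response, interferon response, cell cycle and DNA replication, KMT2 family and COMPASS complex, THO/TREX and mRNA export, spliceosome, muscle-disease and cytoskeletal giants, cytoplasmic ribosomal proteins and mitochondrially encoded genes. Some genes sit in several lists, such as the titin genes in the fast muscle, heart and giants lists. For lists with at least 5 measured members, the median log2 ratio (prior count 0.5 per library) was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list stood apart when its median lay outside the middle 95% of these lists, which describes the libraries and is not a p-value.

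Genes to name were set by a rule before the data were examined. The ddx39 genes came first. Then, per comparison, among genes with a CPM of at least 5 in either library and a symbol that is not a clone name, the 12 highest and 12 lowest by the interval bound nearest to equality were eligible, as were up to 4 members of each list discussed and its 2 most abundant members. Members named outside this rule were chosen after their values were seen, as were the leading RIP-seq features and the genes named as examples of overlaps. Some readings were added after the data were examined. List symbols not found in the table were matched without the zebrafish paralog suffix. The mitochondrial list was restricted to its 13 symbols starting with mt-, since the pattern as written also took nuclear genes. Clone prefixes of letters were read as a prefix followed by digits.

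Alternatives were DESeq2 1.42.0 median-of-ratios size factors, total gene counts, upper-quartile factors, no expression filter, a CPM of at least 5, a 4-fold size, a whole interval beyond 2-fold, and a prior count of 5. The scripts were tested on Poisson counts simulated at a common rate per gene taken from each pair of real libraries. These hold counting error only and no spread between embryos or libraries, so the rates below are not error rates for replicates. Among genes with a CPM of at least 5, 100 were changed 4-fold and 100 were changed 2.5-fold. For the RNA-seq pair 100% and 97% of these were called with the right direction, and 0.878% of 18454 unchanged genes were called. For the RIP-seq pair these values were 92%, 75% and 1.54% of 14981. For RIP-seq against RNA-seq they were 96%, 76% and 1.40% of 18886 with the wild-type label, and 96%, 77% and 1.59% of 19202 with the mutant label. Of 100 lists of 25 genes drawn at random from the RNA-seq genes, 6 stood apart.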

Results

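Whole zebrafish embryos at 24 h post fertilisation were profiled by RNA-seq in wild-type and ddx39a mutant animals, and by RNA immunoprecipitation followed by sequencing (RIP-seq), in which RNA is recovered together with a tagged protein. DDX39A is a DEAD-box RNA helicase with known roles in pre-mRNA processing and mRNA export. The stated purpose was to find transcripts that differ in the mutants and transcripts bound by DDX39A. There were 4 libraries, 1 in each group: wild-type RNA-seq, ddx39a mutant RNA-seq, RIP-seq labelled wild type and RIP-seq labelled ddx39a mutant. The protocol given for both RIP-seq libraries described Flag-tagged ddx39a mRNA injected into mutant embryos and anti-Flag beads, while the genotype labels differed, so both libraries are named by their labels and neither is taken as the mock. With 1 library per group there was no replicate check, and each comparison is between these libraries, not between genotypes. The intervals given are 95% exact conditional binomial intervals and cover counting error only.

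The RNA-seq libraries held 9922182 (wild type) and 9533101 (mutant) reads counted to genes. The RIP-seq libraries held 1966053 (wild-type label) and 2246938 (mutant label), so their ratios carry wider counting error. Ribosomal and unnamed features led both RIP-seq libraries. The features zgc:158463 and si:dkey-153m14.1 took 37.8% and 30.9% of the gene counts with the wild-type label, and 34.6% and 28.9% with the mutant label, against under 0.01% each in RNA-seq. The 5_8S_rRNA gene took 4.96% (exact interval 4.93 to 4.99%) and 3.95% (3.92 to 3.97%). The 5 leading features together held 75.5% of the counts with the wild-type label and 69.5% with the mutant label. In RNA-seq, the top 5 features held 4.15% and 4.08%.

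The gene table gives the symbol DDX39A to 2 zebrafish genes and does not say which one carries the mutation. ENSDARG00000015111 had 3742 counts in wild-type RNA-seq and 706 in mutant RNA-seq, 5.31-fold lower (interval 4.90 to 5.76), the third lowest by the interval bound nearest to equality among named genes with a CPM of at least 5. The other copy, ENSDARG00000006225, had 2242 and 2382 counts, a ratio of 1.06 (1.00 to 1.12). The paralog ddx39b (ENSDARG00000036069) had 677 and 707 counts, a ratio of 1.04 (0.937 to 1.16). In RIP-seq, ENSDARG00000015111 had 318 counts with the wild-type label and 199 with the mutant label, 1.96-fold lower (1.64 to 2.35). ENSDARG00000006225 had 191 and 153 counts, 1.53-fold lower (1.23 to 1.91), and ddx39b had 7 and 14 counts. RIP-seq counts of the DDX39A genes may include the injected Flag-tagged ddx39a mRNA that the protocol describes, so they need not measure the embryos' own mRNA.

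**Figure D1:**
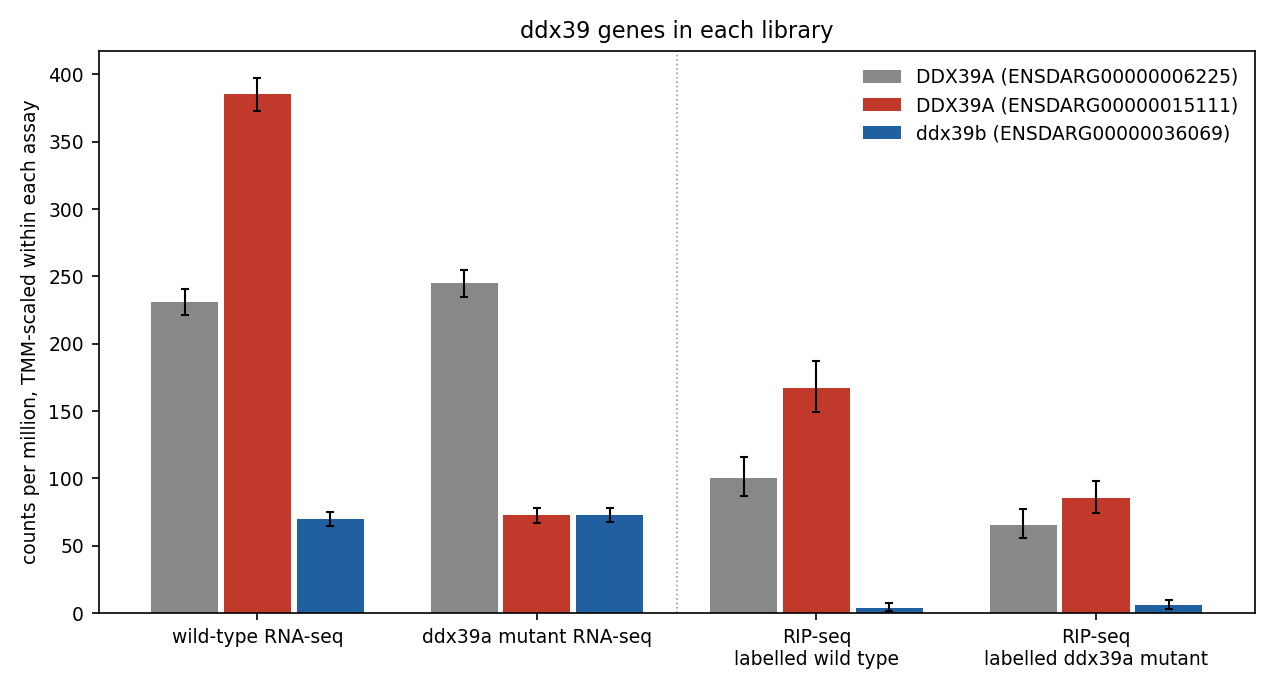
CPM of the 3 ddx39 genes in each of the 4 libraries, TMM-scaled within RNA-seq and within RIP-seq, so that bars are compared within an assay only. Error bars are 95% Poisson intervals of the count, and ENSDARG00000015111 stood at 385 in wild-type RNA-seq and 72.5 in mutant RNA-seq.

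The RNA-seq comparison asked which transcripts differed in ddx39a mutants. Genes of the contractile apparatus of fast muscle and of the lens were lower in the mutant library. Of 40 measured fast sarcomere genes, 17 were at least 2-fold lower and 1, the myosin heavy chain gene myhb, was higher (4.87-fold, 2.24 to 12.1, 39 against 8 counts). Of 30 lens genes, 23 were lower and none was higher. Genes that commit cells to muscle did not follow: among 22 myogenic regulators none was called lower, and the fusion genes MYMK and mymx were each 1.93-fold higher. The globin genes HBE1, hbae1.1 and hbae1.3 were at least 2-fold lower too, HBE1 by 6.13-fold (5.31 to 7.10), while hbae3 was 1.84-fold lower (1.77 to 1.91).

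Over 18800 genes compared, 406 were at least 2-fold higher and 488 lower in the mutant library with an interval excluding equality, a balance that turned to 472 higher and 423 lower with total-count scaling. Of these, 216 and 140 had no symbol or only a clone name. The named genes lowest in the mutant were hbae1.1 (an alpha globin, 17.0-fold, 5.51 to 85.3), HBE1, DDX39A, crygmxl2 (a gamma crystallin, 9.51-fold, 4.59 to 22.8), MIP (the lens aquaporin, 7.51-fold, 4.44 to 13.6) and and3 (8.01-fold, 3.64 to 20.8). Also among the lowest were a gene with the symbol MYL11 (a fast myosin light chain, 3.83-fold, 3.53 to 4.16) and cavin4a (3.82-fold, 3.17 to 4.63). So were CASQ1 (the calcium-storing calsequestrin of the sarcoplasmic reticulum, 3.80-fold, 3.10 to 4.70) and XIRP2 (5.13-fold, 3.29 to 8.32). The highest were RNaseP_nuc (12.2-fold, 4.48 to 46.7), mir219-3 (4.57-fold, 2.97 to 7.28) and pimr93 (5.88-fold, 2.88 to 13.6), all from low counts. Among more abundant genes, her4.4, a Notch target, was 2.56-fold higher (2.13 to 3.10), the transcriptional regulator SPEN 2.28-fold (2.04 to 2.54) and the splicing factor TFIP11 2.18-fold (2.0 to 2.37).

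The fast sarcomere list had a median log2 ratio of -0.90, below all 10000 random lists matched on expression. Parvalbumins, the calcium buffers of fast fibres, were among its lowest members: pvalb4 was 3.74-fold lower (3.03 to 4.66) and pvalb1 2.98-fold (2.75 to 3.22). A titin gene (TTN, ENSDARG00000000563) was 2.84-fold lower (2.7 to 2.98), and the other TTN gene, ENSDARG00000028213, 1.84-fold (1.78 to 1.91). The abundant myosin heavy chain gene myhz1.3 was 2.01-fold lower (1.98 to 2.05) and the calcium pump gene atp2a1 1.74-fold (1.72 to 1.77). Slow muscle genes had a median of -0.44, also below all random lists, with 2 of 15 at least 2-fold lower: tnnt2d (3.75-fold, 2.82 to 5.04) and RYR1 (ENSDARG00000011422, 2.25-fold, 1.98 to 2.55). The most abundant of them, smyhc1, was 1.05-fold lower (1.02 to 1.08). Near-identical myosin, globin and crystallin copies can exchange reads, so values of single copies are uncertain.

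Myogenic regulators had a median of 0.12, at percentile 97.24, inside the middle 95% of random lists, but the median was 0.62 over 10 genes and above all random lists when symbols were matched exactly. The fusion proteins' genes mymx and MYMK had intervals of 1.68 to 2.22 and 1.68 to 2.24. The determination genes MYOD1 and MYOG stood at 1.55-fold (1.34 to 1.80) and 1.66-fold (1.43 to 1.92). Only tbx16 passed the size rule (2.32-fold higher, 1.43 to 3.86). Members on the lower side included the SMYD1 genes, whose products act in myosin assembly, at 1.76-fold (1.65 to 1.88) and 1.80-fold lower (1.54 to 2.12). Heart genes had a median of -0.04 (0.02 with total-count scaling, percentile 27.75), with 3 of 28 lower, among them nppa (6.21-fold, 2.39 to 20.5, 5 against 31 counts), and 1 higher, myh7bb (2.07-fold, 1.86 to 2.31).

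Lens genes had the lowest median of all lists, -1.44, below all random lists. The gamma crystallin gene crygm2d10 was 22-fold lower (5.75 to 188), and the beta crystallin gene crybb1l2 3.07-fold (2.64 to 3.59). No reads were counted for crygm2d12 in the mutant against 30 in wild type, at least 10-fold lower with the floor of 3 counts per library. Erythroid genes had a median of -0.30, below all random lists, with 4 of 23 lower and 1 higher. They included hbae1.3 (3.81-fold, 3.08 to 4.74) and SLC4A1, the red cell anion exchanger (2.66-fold, 2.4 to 2.96). The higher member was the mitochondrial iron importer SLC25A37 (2.16-fold, 1.68 to 2.81). Neuronal genes had a median of -0.36, below all random lists, with only the neurofilament genes NEFL and nefla passing the size rule, at 3.0-fold (1.31 to 7.74) and 3.41-fold (1.21 to 11.8) lower. None of 34 neural crest and cartilage genes passed it, but their median was -0.19 (percentile 0.05), with COL2A1 (ENSDARG00000069093) 1.77-fold lower (1.71 to 1.82) and COL11A2 1.78-fold lower (1.65 to 1.92).

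The KMT2 and COMPASS, THO/TREX and spliceosome lists had medians slightly above their random lists in the main setting. The KMT2 family and COMPASS list, which holds histone methyltransferases and their partners, had a median of 0.17, above all random lists, with none of 28 members called. KMT2E was 1.75-fold higher (1.60 to 1.92), kmt2bb 1.64-fold (1.53 to 1.76) and kmt2a 1.54-fold (1.45 to 1.63). In the THO/TREX and mRNA export list (median 0.09, percentile 97.84), the export adaptor alyref was 1.77-fold higher (1.72 to 1.83), ddx19a was 2.66-fold higher (1.59 to 4.63), and DDX39A was the 1 lower member of 25. The spliceosome list had a median of 0.04 (percentile 99.60) and no called member among 82. The THO/TREX list moved inside the middle 95% of random lists when a CPM of at least 5 was required (percentile 96.71), and the spliceosome list when symbols were matched exactly (95.69). Counts of called genes fell to 114 higher and 194 lower with the stricter CPM filter.

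**Figure D2:**
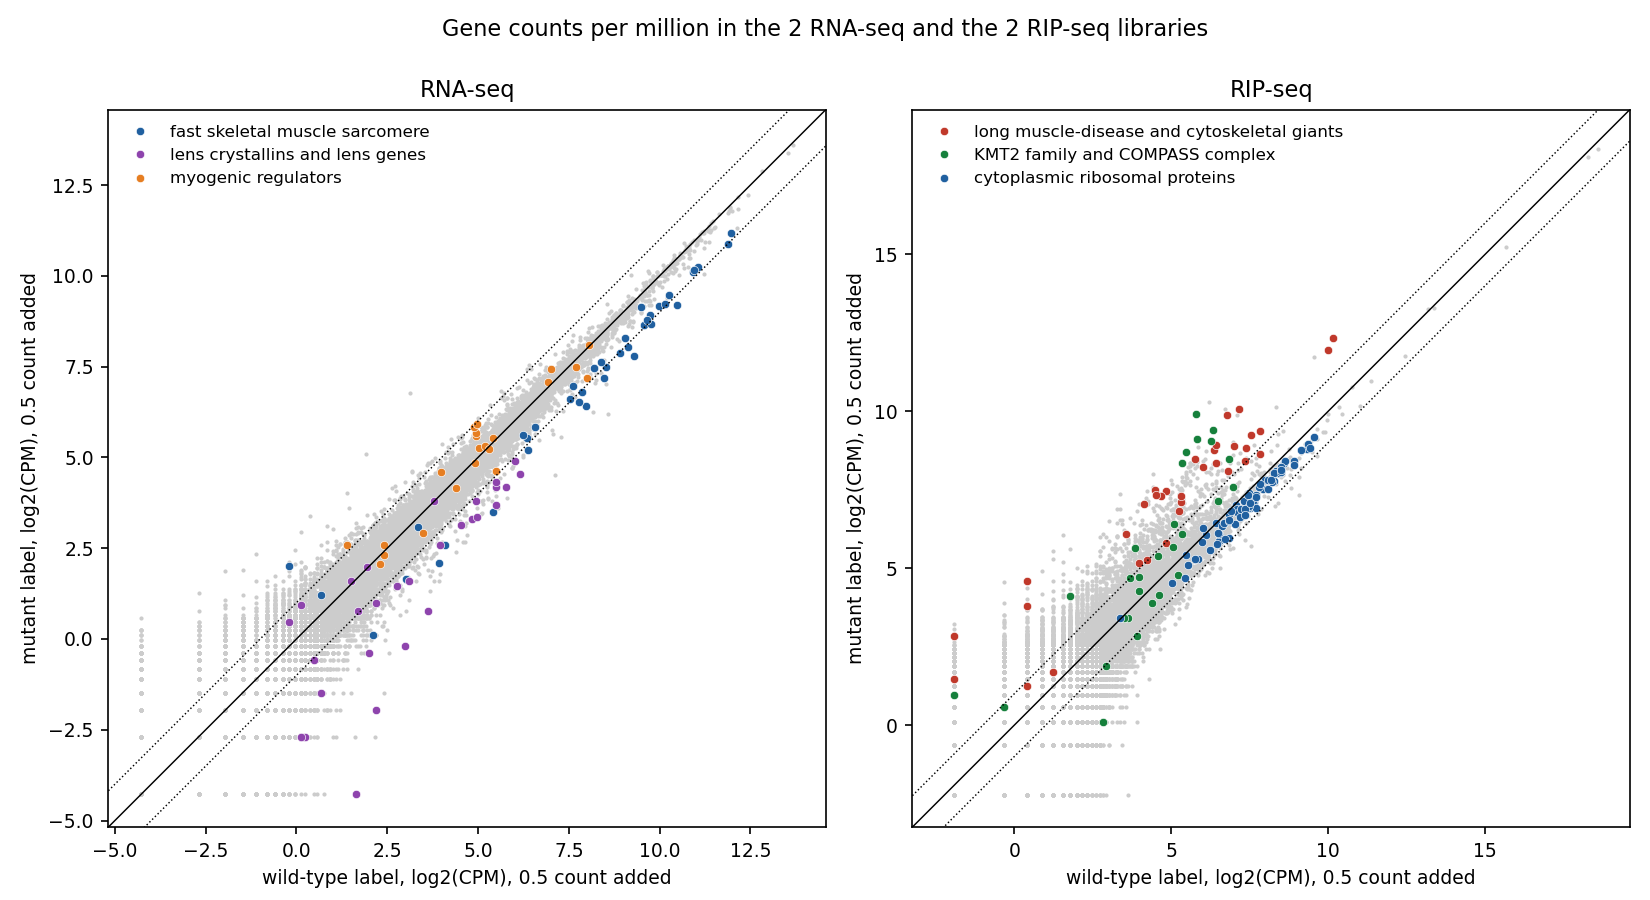
Each gene's log2 CPM (0.5 count added, TMM-scaled) in the mutant-labelled library against the wild-type-labelled library, for RNA-seq on the left and RIP-seq on the right. Grey points are all genes, coloured points are members of the named lists, the solid line is equality and dotted lines are 2-fold; 17 of 40 fast sarcomere genes lay at least 2-fold lower in RNA-seq and 29 of 34 genes for giants at least 2-fold higher in RIP-seq.

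The RIP-seq libraries with the mutant and the wild-type label were compared as a pair that the design names, with the limit on their labels given above. Genes for muscle-disease and cytoskeletal giants were higher in the library labelled mutant. Of 34 measured, 29 were at least 2-fold higher and none was lower. KMT2 genes showed the same direction: kmt2a was 17.7-fold higher (14.5 to 21.7), kmt2bb 9.88-fold (8.10 to 12.2), KMT2D 8.58-fold (7.25 to 10.2) and KMT2C (ENSDARG00000079312) 9.45-fold (7.56 to 12). The ribosomal protein list was on the lower side, with no member called.

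Among 15762 genes compared, 1319 were at least 2-fold higher and 835 lower with the mutant label. The named genes with the highest conservative ratios were kmt2a, the epiplakin gene eppk1 (17.0-fold, 14.4 to 20.4), herc7 (25.1-fold, 10.5 to 78.5), the transcriptional repressor cica (16.4-fold, 10.3 to 27.5), znf469 (12.2-fold, 8.82 to 17.2) and the chromatin remodeller srcap (10.2-fold, 8.79 to 11.8). The lowest rested on few counts: mapk13 had 1 against 20 (24.5-fold, 3.92 to 1016), TGM2 6 against 37 (7.56-fold, 3.16 to 21.9), and ATP1B4 0 against 14, at least 5.72-fold lower.

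The list of giants had a median log2 ratio of 2.09 in RIP-seq, above all random lists, and 1.99 with members at 0 counts set to their bound. The spectraplakin gene macf1a was 8.60-fold higher (7.45 to 9.96), the plectin gene pleca 7.52-fold (6.64 to 8.56) and the TTN genes 4.53-fold (4.32 to 4.74, ENSDARG00000028213) and 3.94-fold (3.75 to 4.14, ENSDARG00000000563). In the KMT2 and COMPASS list 11 of 28 members were higher and 2 lower, with a median of 0.79 (percentile 99.97; 0.76 with zeros at their bound). Besides the KMT2 genes, the higher members were KDM6B (3.16-fold, 2.72 to 3.69), kdm6al, setd1a, SETD1B and psip1b, and the lower ones were CXXC1 and pagr1. KMT2E was 1.76-fold higher (1.22 to 2.56), under the size rule.

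Fast sarcomere genes split in RIP-seq: 10 of 38 were lower, among them ckma (3.54-fold, 2.87 to 4.4) and tpma (2.53-fold, 2.2 to 2.92), and 6 were higher, all of them nebulin, titin or ryanodine receptor genes. Their median was -0.68, below all random lists, and -0.52 with zeros at their bound. Slow muscle genes had a median of -0.58 (percentile 0.44) and erythroid genes one of -0.97 (percentile 0.03). With zeros at their bound the medians were -0.30 and -0.41. These values lay inside the range of random lists, but that range kept the prior count of 0.5, so the 2 sides were not treated alike. The globin gene hbae3 was 2.95-fold lower (2.24 to 3.92). None of 80 ribosomal protein genes was called, and their median was -0.39, below all random lists. Epidermal genes had a median of -0.42 (percentile 0.13), with the keratin gene cyt1 2.54-fold lower (2.22 to 2.92). The slow muscle list moved inside the random range with a CPM of at least 5 (percentile 9.04). A change to total-count scaling shifted all log2 ratios of this pair by 0.10.

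**Figure D3:**
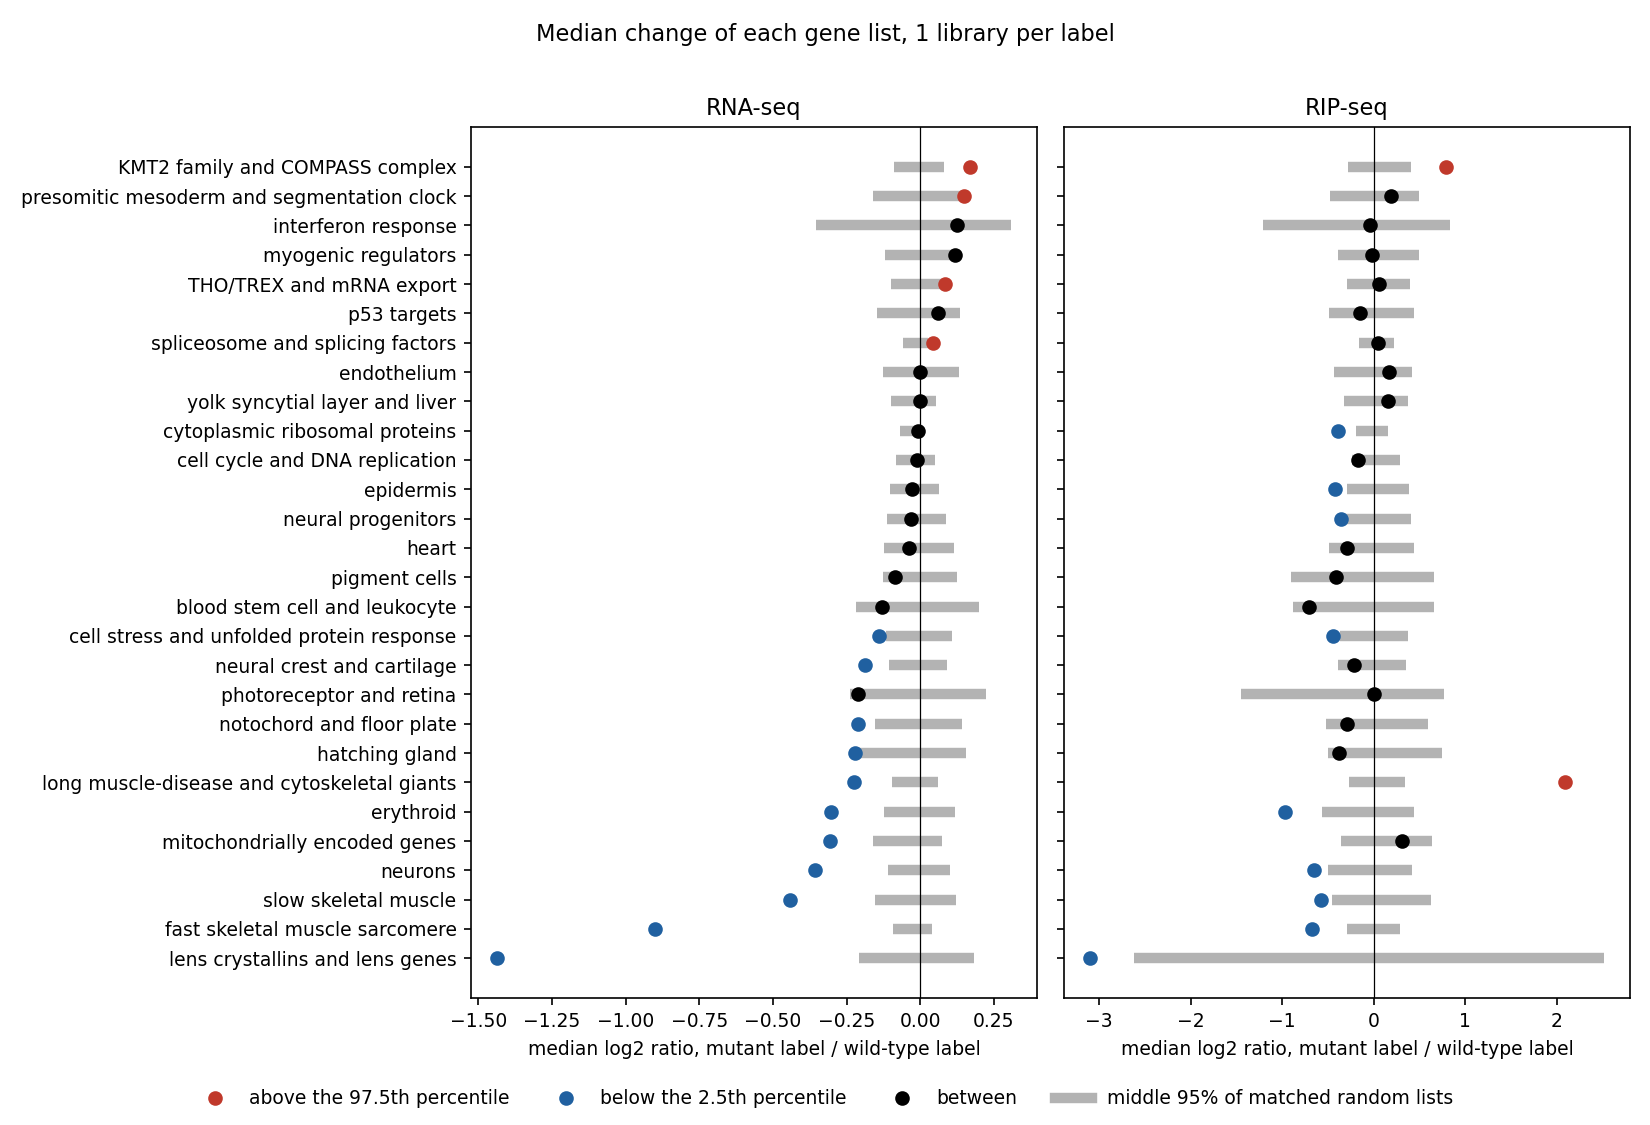
Median log2 ratio of each gene list, mutant label over wild-type label, in RNA-seq (left) and RIP-seq (right). Points are list medians, grey bars the middle 95% of 10000 expression-matched random lists; the giants stood at -0.23 in RNA-seq and 2.09 in RIP-seq, and the lens list in RIP-seq rested on 9 genes, 7 of them with 0 counts in a library.

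RIP-seq was compared with RNA-seq of the same label to describe which RNAs had higher or lower counts relative to RNA-seq. The labels' protocols give oligo(dT) enrichment for the libraries, so RNA-seq counts do not give the embryo level of RNAs without poly(A) tails. RIP-seq nonetheless held many counts of such RNAs, such as 5_8S_rRNA, so the RNA content of the assays differed. Ratios below, of genes and of lists, therefore cannot tell recovery from a difference in RNA content or preparation between the assays. The genes 5_8S_rRNA (a ribosomal RNA), U2, rn7sk and h1l1 were among the 12 named genes with the highest conservative ratios under both labels. The lists below the random range under both labels were the mitochondrial, ribosomal protein, yolk, pigment, fast sarcomere, lens, neuron, erythroid and neural crest lists. With zeros at their bound, the lens medians (-1.15 and -1.14) and the neural crest median with the mutant label (-0.29) lay inside the random range. The neural crest list with the mutant label also lay inside it with a CPM of at least 5 (percentile 2.77) and with exact symbols (3.88). The list of giants was higher with the mutant label. The 5_8S_rRNA gene had 97454 counts against 3 with the wild-type label and 88705 against 1 with the mutant label. The RNA of the small nuclear ribonucleoprotein complex that represses transcription elongation, rn7sk, was 367-fold higher (298 to 455) and 280-fold higher (232 to 340). The spliceosomal RNA gene U2 had no RNA-seq counts and was at least 1144-fold and 1104-fold higher against the floor. Few or no RNA-seq counts after oligo(dT) enrichment need not mean a low level in the embryo, so the folds of 5_8S_rRNA, U2 and rn7sk are not recovery over that level. The linker histone gene h1l1 was 16730-fold (2995 to 661506) and 5974-fold higher (1648 to 49412). The wide intervals of h1l1 reflect few RNA-seq counts, so its folds are not recovery over the embryo level either.

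Mitochondrially encoded genes were lower in RIP-seq than in RNA-seq for 12 of 13 members under each label, and the other, mt-atp8, was not called with the wild-type label and was 3.04-fold higher (1.03 to 7.46, 6 against 29 counts) with the mutant label, though lower there with total-count scaling. The list medians were -2.97 and -2.43, below all random lists. MT-CO2 was 19.6-fold lower (15.5 to 25) and 14.7-fold lower (12.2 to 17.9). Ribosomal protein genes were lower for 45 of 80 members with the wild-type label and 59 of 80 with the mutant label, RPS29 by 11.3-fold (9.12 to 14.1) and 12.1-fold (9.71 to 15.3). Yolk and liver genes had medians of -2.23 and -1.95, below all random lists (-2.01 and -1.82 with zeros at their bound), with apoc1 11.1-fold (8.49 to 14.9) and 9.23-fold lower (7.41 to 11.6). Pigment cell genes had medians of -1.86 and -2.08 (-1.26 and -1.27 with zeros at their bound), with gch2, of pteridine synthesis, 24.8-fold (11.4 to 67.5) and 43.9-fold lower (17.1 to 161). Among fast muscle genes the troponin gene TNNT3 (ENSDARG00000068457) was 47.8-fold (18.7 to 176) and 48.4-fold lower (13.4 to 400), while the titin gene ENSDARG00000000563 was 5.62-fold (5.34 to 5.92) and 63.0-fold higher (60.1 to 66.0).

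The giants had a median of 0.57 with the wild-type label, above all random lists, which became -1.26 with total-count scaling, and 2.79 with the mutant label, where 31 of 34 were at least 2-fold higher. For KMT2 and COMPASS genes, the median with the mutant label was 1.06, above all random lists, with 15 of 29 members higher and 5 lower; it became -0.73 with total-count scaling and lay inside the random range with exact symbols (percentile 93.47). KMT2D was 16.0-fold higher (14.9 to 17.2) and kmt2a 12.5-fold higher (11.9 to 13.3) there. With the wild-type label the median was 0.23 (percentile 94.47), and KMT2D was 2.35-fold higher (1.97 to 2.78) but lower, at a log2 ratio of -0.60, with total-count scaling. Of the ddx39 genes, DDX39A ENSDARG00000015111 was 1.53-fold (1.36 to 1.71) and 4.15-fold higher (3.53 to 4.86), and with total-count scaling it was lower under the wild-type label. Its counts were 318 against 3742 with the wild-type label and 199 against 706 with the mutant label. The larger ratio with the mutant label thus goes with the lower RNA-seq count and not with more RIP-seq counts. The copy ENSDARG00000006225 was 1.53-fold higher (1.31 to 1.78) with the wild-type label and 1.06-fold lower (0.898 to 1.25) with the mutant label, and lower under both with total-count scaling. The ddx39b gene was 5.38-fold (2.6 to 13.4) and 3.43-fold lower (2.03 to 6.31). Because the RIP-seq protocol describes injected ddx39a mRNA, the ratios of the DDX39A genes need not be those of the embryos' own mRNA.

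With the wild-type label, 1568 genes were higher and 2450 lower of 17412, and with the mutant label 2441 were higher and 2875 lower of 17711. These splits depended on the scaling, since a few features took most RIP-seq counts. Scaling to total gene counts shifted the log2 ratios by -1.83 and -1.79 and gave 310 higher and 13429 lower, and 500 higher and 12946 lower. Upper-quartile factors shifted them by 0.16 and 0.15 and gave 2006 higher and 1934 lower with the wild-type label, and 2828 higher and 2399 lower with the mutant label. Among 16580 genes compared under both labels, 662 were higher under both, against 168 for independent lists, and 1495 were lower under both, against 424. Across 11743 genes with a CPM of at least 1 in each library, the RIP-seq over RNA-seq log2 ratios of the 2 labels correlated with Pearson's r = 0.670 and Spearman's rho = 0.623. Genes are not independent replicates, so no p-value is given.

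The mutant against wild-type log2 ratios of RNA-seq and RIP-seq were only weakly related across the same genes, with Pearson's r = 0.083 and Spearman's rho = 0.076. With a CPM of at least 5 in each library, r was 0.135. Of 15095 genes compared in both, 22 were higher in both, against 16.0 for independent lists, among them SPEN, rfx5 and myh7bb. Another 21 were lower in both, against 11.4, among them HBE1, pvalb2, MYL11 and hbae1.3. Lower in RNA-seq but higher in RIP-seq were 7 genes, against 18.3, with the muscle genes TTN and RYR1 among them, and 3 genes were higher in RNA-seq but lower in RIP-seq, against 9.95.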

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

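The tests in this part were chosen after the results were seen.

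The list of muscle-disease and cytoskeletal giants moved in opposite directions under the same contrast: its median log2 ratio of mutant over wild-type label was 2.09 in RIP-seq and -0.23 in RNA-seq. The difference itself was not tested, since each assay had 1 library per label. The comparisons do not use the files' summary rows. There, alignments to more than 1 place made up 91.8% of records in RIP-seq with the wild-type label and 89.5% with the mutant label. In RNA-seq they made up at most 11.2%.

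KMT2 genes were 1.76 to 17.7-fold higher in the RIP-seq library labelled mutant. The choice among 4 scalings changed this little, with the median fold of the 7 KMT2 genes between 8.41 and 9.20. The alternatives shift the log2 ratios of this pair only by -0.03 to 0.10 from TMM. They could not have removed the difference, and a scaling error shared by all 4 was not tested. The mRNA levels of the RNA-seq libraries differed by less than this for the 6 genes other than KMT2E. Their RNA-seq folds had a median of 1.41 and upper bounds up to 1.76, against lower bounds of at least 5.83 in RIP-seq. For KMT2E, at 1.75-fold in RNA-seq and 1.76-fold in RIP-seq, a higher mRNA level stays open. No library gives the input RNA of the RIP-seq embryos, so a difference in mRNA level between those embryos is not excluded for any of the 7 genes. A candidate explanation that stays open is recovery that depends on transcript length and differed between the RIP-seq libraries, since the giants had a median log2 ratio of 2.09 and the ribosomal protein genes, with short transcripts, one of -0.39. Capture by DDX39A beyond that of the giants may add to it, as the KMT2 median lay at percentile 99.74 of 10000 draws of 7 genes from the 34 giants, with 5 giants at or above it, but the KMT2 genes had been singled out for high ratios, lengths were not used and no library is named as the mock, so capture cannot be told apart from length here.

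Sarcomere genes were lower in the mutant RNA-seq library while myogenic regulators were not. Fewer muscle cells of all stages could lower both. The regulators had a median log2 ratio of 0.12, against -0.90 for the fast sarcomere list. With exact symbols the regulators' median was 0.62 over 10 genes. A bootstrap over the genes of the regulator list gave a 95% interval of -0.09 to 0.41, which holds no spread between embryos or libraries. Some regulators also sit in lists of other tissues, such as tbx16 in the presomitic mesoderm list. Their median need not follow the number of muscle cells, so fewer muscle cells are not excluded. A developmental delay may contribute: presomitic mesoderm genes, expressed early, lay at percentile 97.64, at 99.98 with exact symbols and at 97.43 without an expression filter, the last inside the middle 95% of random lists. These libraries do not settle it. Impaired maturation of muscle fibres remains open and was not tested.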

How the results depend on the processing

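The exact matching of list symbols and the mitochondrial pattern as written were chosen after seeing the data, and all other alternatives were set before. No paired analysis was possible because each group had 1 library and no result came from a test across replicates, so libraries could not be left out in turn either. Under alternatives, 753 list results kept their place outside or inside the random range, 14 moved out of it, 15 moved into it on the same side of its middle and 1 crossed its middle. DESeq2, total-count and upper-quartile factors gave 112, 111 and 112 of the kept places. These factors shift a list and its random lists alike, so a place could change only through which genes pass the expression filter. Those kept places therefore say little about robustness. The sign of the median is another matter: of 28 lists, total-count scaling changed it for 7 in RNA-seq, 2 in RIP-seq, and 9 and 8 in RIP-seq over RNA-seq with the wild-type and the mutant label, and upper-quartile factors for 2, 1, 4 and 4. DESeq2 factors changed it for 2 in RIP-seq and for none in the other comparisons. Of the counts of called genes, 34 stayed within 1.5 times the main count and 22 did not. Of the ratios of named genes, 1597 stayed inside their counting interval, 299 moved beyond it and 27 that had been called higher or lower changed sign. Sign changes of genes not called, such as DDX39A with the wild-type label, are not in the last number. The cause of changes was not tested beyond what a setting does by construction: stricter sizes and filters leave fewer genes, and total-count scaling shifts every ratio. Depth limits the RIP-seq ratios, where 2.5-fold changes were recovered for 75% of simulated genes against 97% in RNA-seq.

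In RNA-seq, a CPM of at least 5 gave 114 genes higher and 194 lower, a 4-fold size 99 and 114, and a whole interval beyond 2-fold 43 and 110. In RIP-seq, the 4-fold size gave 564 and 367 and the whole interval 440 and 74. For RIP-seq against RNA-seq these were 758 and 1223, and 590 and 724, with the wild-type label, and 1221 and 1348, and 1329 and 906, with the mutant label. Total-count scaling gave 310 and 13429, and 500 and 12946. All 27 of these sign changes were of RIP-seq over RNA-seq with total-count scaling, which shifts these log2 ratios down. With the wild-type label their values were tnnt2c (-0.070), PRDM1 (-0.054), MYOG (-0.16), SPI1 (-0.36), IKZF1 (-0.36), flt1 (-0.31), col8a1a (-0.81), GADD45B (-0.50), hsp90aa1.1 (-0.78), dnajb1a (-0.0051), RRM2 (-0.79), KMT2D (-0.60), KMT2C (-0.55), KMT2C (-0.75), THOC5 (-0.60) and obscnb (-0.17). With the mutant label they were NOTCH3 (-0.68), NOTCH1 (-0.54), stab2 (-0.18), stab1 (-0.60), col8a1a (-0.40), APOB (-0.54), DDIT4 (-0.077), cenpe (-0.12), mcm3ap (-0.31), mt-atp8 (-0.097) and THOC2 (-0.66). The interferon list with the mutant label moved to percentile 48.74.

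In RNA-seq, lists moved across the edge of the random range as follows. With a CPM of at least 5, THO/TREX lay at percentile 96.71. With exact symbols, myogenic regulators lay at 100, notochord at 3.0 and the spliceosome at 95.69. Without a filter, presomitic mesoderm lay at 97.43. In RIP-seq, a CPM of at least 5 put neurons at 5.92 and slow muscle at 9.04, and exact symbols put neural progenitors at 2.62 and pigment cells at 0.29.

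For RIP-seq against RNA-seq with the wild-type label, presomitic mesoderm moved to 50.48 with a CPM of at least 5. Exact symbols put heart at 0.82, myogenic regulators at 99.40 and retina at 1.11. Cell stress moved to 98.03 without a filter and to 97.58 with the prior count of 5. With the mutant label, a CPM of at least 5 put interferon at 88.94, neural crest at 2.77 and neural progenitors at 0.82. Exact symbols put KMT2 at 93.47, neural crest at 3.88, neural progenitors at 0.82, retina at 97.91, presomitic mesoderm at 99.62 and the spliceosome at 5.32. Without a filter, interferon lay at 81.83, neural progenitors at 2.39 and presomitic mesoderm at 99.34, and with the prior count of 5 interferon lay at 83.82 and neural progenitors at 0.25.

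Across genes, r between RNA-seq and RIP-seq ratios was 0.135 with a CPM of at least 5 in each library. Between the labels, r of RIP-seq over RNA-seq was 0.736 with that filter and 0.772 with the prior count of 5.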

Other observations

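The tissue lists not described so far were mostly near their matched random lists in RNA-seq. None of 25 endothelial, 25 epidermal, 25 pigment cell, 28 yolk and liver, 27 p53 target, 10 interferon, 39 cell cycle or 81 ribosomal protein genes was called higher or lower. Their median log2 ratios lay at percentiles 48.30, 38.34, 9.16, 67.90, 82.42, 80.36, 55.14 and 84.80. Epidermal keratin genes stood out for precision more than size, with krt4 at 121390 counts in mutant and 127338 in wild type, 1.05-fold lower (1.04 to 1.06), and cyt1 1.59-fold higher (1.53 to 1.66). Neural progenitor genes lay at percentile 32.58, with the Notch targets her4.4, her4.2 (1.79-fold, 1.55 to 2.06) and her15.1 (1.67-fold, 1.46 to 1.92) on the higher side. Retinal genes lay at percentile 3.93 with 1 of 16 lower, the ganglion cell gene POU4F2 (2.34-fold, 1.15 to 5.05). Blood stem cell and leukocyte genes lay at percentile 11.43 with 2 of 20 lower, including the macrophage gene MPEG1 (3.08-fold, 1.61 to 6.28).

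Several lists shifted by less than 2-fold in RNA-seq. Notochord and floor plate genes had a median log2 ratio of -0.21 (percentile 0.35, but 3.0 with exact symbols, inside the random range), with CAVIN1 (ENSDARG00000076411) 2.74-fold lower (1.96 to 3.88). Hatching gland genes had one of -0.22 (percentile 2.08), with he1.1 1.3-fold lower (1.26 to 1.35) and he1.3 1.68-fold higher (1.36 to 2.1). In the mitochondrial list, with a median of -0.31 (percentile 0.07), the lower members were mt-atp8 (5.08-fold, 3.39 to 7.84) and mt-nd4l (2.11-fold, 1.93 to 2.3), while MT-CO2 was 1.05-fold lower (1.03 to 1.07). The cell stress list had a median of -0.14 (percentile 0.89) although its called members were higher: the heat shock genes hsp70l (3.15-fold, 1.88 to 5.49) and hsp70.3 (2.26-fold, 1.83 to 2.82). The chaperone gene HSPA5 was 1.26-fold lower (1.2 to 1.33), under the size rule. Presomitic mesoderm genes had a median of 0.15 (percentile 97.64), with tbx16 and her11 higher and EVX1 lower. The giants had a median of -0.23, below all random lists, with 2 of 34 lower, both of them muscle genes, TTN (ENSDARG00000000563) and RYR1 (ENSDARG00000011422).

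In RIP-seq, apolipoprotein B genes were higher: APOB was 8.61-fold (7.46 to 9.98) and apobb.1 4.53-fold higher (4.28 to 4.79) with the mutant label, while the yolk and liver list as a whole had a median of 0.15 (percentile 83.06). The neural progenitor list had a median of -0.36 (percentile 1.96, but 2.62 with exact symbols, inside the random range), with 2 of 21 members lower, SOX1 and FABP7, and 3 higher, NOTCH3 (3.85-fold, 3.18 to 4.68) and 2 NOTCH1 genes (3.14-fold, 2.36 to 4.24, and 2.08-fold, 1.67 to 2.6). Neuronal genes had a median of -0.65 (percentile 0.58, but 5.92 with a CPM of at least 5, inside the random range) and stress genes one of -0.45 (percentile 0.70). The lens list had 9 measured genes and 7 with 0 counts in a library, so its median of -3.10 became -0.29 with those genes at their bound and carries no direction. At a CPM of at least 5, 73 genes called higher had a ratio at or above the KMT2 median.

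Some tests were run after the results were seen and are left out here with their values known. Tests of whether RNAs without poly(A) tails led RIP-seq are not reported, because the genes were chosen for the pattern or no outcome would have counted against it. A test of whether genes near a ddx39a gene shared its shift is not reported, because few neighbours were measured, the windows were not matched in size and no table tied the mutated copy to a gene ID.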
